A study of Mus musculus with 6 samples.

How the data were processed

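RNA from adult microglia, the resident macrophages of the brain, was sequenced from 10-month-old C57BL/6 mice that were wild type (WT) or labelled Selk-/-, a knockout of Selenok. There were 3 libraries per group. Groups came from the genotype labels, and the replicate numbers used here are names only. The labels do not say whether each library came from a separate animal, so p-values measure only the spread between these libraries, which may be partly technical. Xist and Ddx3y, given below, differed between libraries within each group, which argues against repeats of the same animal. The title of replicate 3 in each group carries 2 numbers, and whether these libraries are pools is not given in the sources used here.

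The deposited table holds raw counts per gene and FPKM (fragments scaled by gene length and library size) for the 6 libraries, for 55414 Ensembl genes. Per the labels' protocols, the authors aligned reads with Hisat2 2.0.5, quantified genes with stringtie 2.2.0 and tested them with DESeq2 1.20.0, calling genes that differed at least 2-fold with P under 0.05. The sequencing depth they state is 10 G per sample. Per the submitters' processing notes, Bowtie 0.12.2 and the builds mm8 and mm9 were used, which contradicts the protocol. The table names no build, and positions are printed as it gives them. They are not those of GRCm38: of 52081 gene IDs also found in GENCODE M21, 1499 had the same start. Strand handling and the treatment of reads that map to several places are not given in the sources used here. Nuclear copies of mitochondrial genes carried high counts (Gm28437, 63467 in WT replicate 1), so reads of near-identical genes may be counted at each copy, and values of genes with such copies are uncertain. The table gave a symbol for 32704 genes. A further 20334 were named by gene ID from a reference table of names, and 2376 had no symbol.

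The deposited counts were tested with edgeR 4.0.16 in R 4.3.3: TMM normalisation, filterByExpr over the 2 groups, robust quasi-likelihood fits and Benjamini-Hochberg adjustment at 0.05, two-sided, with no covariate. The filter kept 17739 of 33412 genes with any count. CPM values (counts scaled to a common library total) use the TMM-scaled totals unless stated otherwise. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. Fixed gene lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM, prior count 2, with a preset correlation of 0.01 and adjustment over 34 lists, of which 21 cover processes and 13 hold markers of other cell types. Selenok was left out of every list. Summed marker CPM was compared by a two-sided exact permutation test, whose smallest p with 3 against 3 libraries is 0.1.

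The design, the lists and the first alternatives were set before the data were examined. The alternatives were DESeq2 size factors in edgeR, library size only, no filter, at least 10 CPM in 3 libraries, DESeq2 1.42.0, limma-voom with sample weights, limma on log2(FPKM + 1) and log2(FPKM + 0.1), an estimated correlation in camera, fry, each library left out in turn, and both libraries with 2 numbers in the title left out. FPKM fits kept genes with a mean of at least 1, or all genes. Named genes follow a rule set with the design: Selenok, Cd36 and Zdhhc6; up to 5 genes per direction with the smallest p, a mean CPM of at least 1 and no overlap between groups where none passed the threshold; and the 2 most abundant members of each list past its test. Not every gene that the rule takes is reported here. Genes outside the rule whose changes are given are said to be chosen after their values were seen.

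The edgeR and camera steps were tested on simulated data for the comparison of the 2 groups, over 17494 genes. Of these, 200 were changed 1.5-fold, 2-fold or 4-fold, and 20 lists of 20 other genes were shifted by 0.3 in log2. The edgeR test called 32.8% of genes changed 1.5-fold, 68.7% of those changed 2-fold and 89.4% of those changed 4-fold, with 16 false calls. Camera called 20 of 20 shifted lists and 0 of 20 unshifted lists. Genes were drawn independently of each other and without a split between libraries, so these rates need not hold for the data. Totals per library were 21112082 to 28123871 counts, so 3 counts correspond to 0.107 to 0.142 CPM of the unscaled total. Within groups, pairs of libraries differed by a chi-square of 14.8 to 39.9 per degree of freedom, so none was treated as a duplicate.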

Results

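Gene expression was measured by RNA sequencing in microglia from brains of 10-month-old mice, in 3 WT libraries and 3 labelled Selk-/-. Total counts were 27562741, 26694358 and 28123871 in WT replicates 1 to 3, and 27541487, 26026236 and 21112082 in replicates 1 to 3 labelled Selk-/-. Pearson correlations of log2 CPM across genes were 0.972 to 0.987 within groups and 0.964 to 0.987 between them; genes are not independent replicates. The libraries did not split by group alone. Small nucleolar RNA genes held 322, 318 and 324 CPM (of the unscaled total) in WT and 327 in replicate 1 labelled Selk-/-, but 46.0 and 54.9 in replicates 2 and 3 labelled Selk-/-. The mitochondrial 16S ribosomal RNA was also lowest in those 2 libraries, at 1988 and 2739 CPM, against 3348 to 4173 CPM in the other 4. Only replicate 1 labelled Selk-/- is on the same side of this split as WT, and values with the split as a block, added after the data were seen, rest on that 1 library.

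The first question was whether the targeted gene was lower in the libraries labelled Selk-/-. Selenok (ENSMUSG00000042682, chromosome 14, 29690265 to 29697619 in the deposited table) encodes a selenoprotein of the endoplasmic reticulum membrane. It was present at 112, 125 and 120 CPM in WT and at 112, 108 and 109 CPM in the libraries labelled Selk-/-. The means were 119 ± 6.57 CPM (SD, n = 3) and 110 ± 2.19 CPM (SD, n = 3). The log2 fold change was -0.12 (SE 0.067, 95% interval -0.27 to 0.04; edgeR adjusted p = 0.381), within the spread between libraries. Gene totals do not show which part of the transcript the reads came from, so a deletion inside the gene is not excluded by them. The count therefore does not check the labels, and every direction given here is drawn between libraries labelled Selk-/- and WT.

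The series title names CD36 palmitoylation. Cd36, a scavenger receptor for lipids and amyloid, lies on chromosome 5 (17986688 to 18093799) and was lower in each of the 3 libraries labelled Selk-/- than in any WT library. It had 34.9 ± 2.98 CPM in WT and 20.8 ± 5.31 CPM in the libraries labelled Selk-/- (SD, n = 3 each). The log2 fold change was -0.75 (SE 0.188), which missed the edgeR threshold (adjusted p = 0.127) and passed that of DESeq2 (adjusted p = 0.0026). With the snoRNA split as a block it was -1.24 (edgeR adjusted p = 0.196), and with the border macrophage score as a covariate, also added after the data were seen, -0.26 (edgeR adjusted p = 0.702). That score, the mean log2 CPM of the border macrophage list, was 6.01 to 6.51 in WT and 4.94 to 5.79 in the libraries labelled Selk-/-. It separated the groups, so this covariate also takes up part of the label difference. Zdhhc6, the palmitoyltransferase known to partner SELENOK, lies on chromosome 19 (55259723 to 55304464) and had 30.1 ± 1.97 and 33.1 ± 2.502 CPM (SD, n = 3 each), a log2 fold change of 0.14 (edgeR adjusted p = 0.427). It overlaps Acsl5 on the opposite strand, so its count is uncertain.

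**Figure D1:**
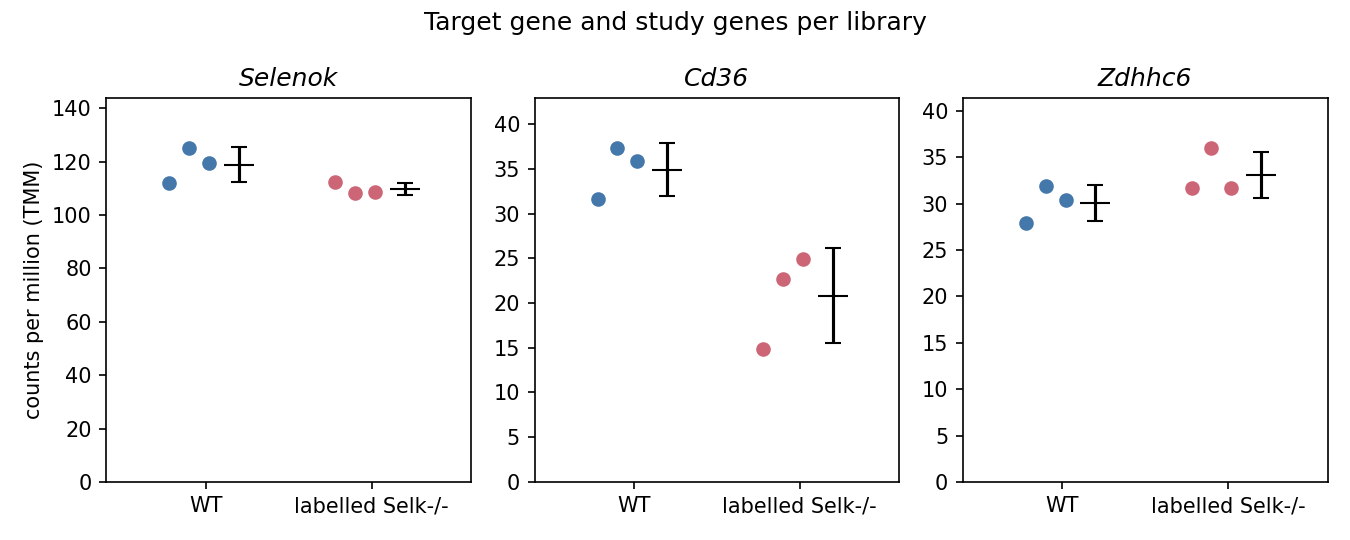
CPM (TMM-scaled) of Selenok, Cd36 and Zdhhc6 in each library, by group; points are libraries and bars give the mean ± SD of 3. Selenok lies between 108 and 125 CPM in all 6 libraries, while Cd36 is 31.6 to 37.3 CPM in WT and 14.8 to 24.9 CPM in the libraries labelled Selk-/-.

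Across the transcriptome, the genes with the smallest p included both higher and lower genes. Mt2, a metal-binding metallothionein, was at 62.4 ± 7.32 CPM in WT and 110 ± 8.91 CPM in the libraries labelled Selk-/- (SD, n = 3 each), a log2 fold change of 0.81. The matrix protease Adamts9 had a log2 fold change of 1.69 (6.33 to 20.3 CPM), the angiogenic factor Angpt2 0.88, the peptide transporter Slc15a2 0.77 and the nucleosome-binding Hmgn5 0.70. In the other direction, the orphan receptor Gpr165 was at -1.002 (32.7 to 16.3 CPM), the synaptotagmin Syt15 at -0.94, the mitochondrial membrane protein Mpv17 at -0.73, the class I molecule H2-T23 at -0.72 and the potassium channel Kcnk13 at -0.55. The rule takes only genes without overlap between groups, so that these 10 separate the groups is no result. Each had an edgeR adjusted p of 0.105, so none passed there. DESeq2 called each of them, at an adjusted p of 4.8e-05 or less. Adamts9 and Angpt2 overlap genes on the opposite strand (9530026P05Rik and Mcph1), and H2-T23 has close paralogs, so their counts are uncertain.

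With edgeR, 0 genes passed adjusted p 0.05, and 3383 had an unadjusted p under 0.05 (1656 higher, 1727 lower) where 887 would be expected with no difference. DESeq2 called 972 genes (500 higher, 472 lower), of which 970 were among those 3383 and 972 had the same sign in edgeR. limma-voom and limma on FPKM called 0, with unadjusted counts of 3680 and 3002. The submitters' rule, at least 2-fold and unadjusted p under 0.05, took 209 genes in the edgeR fit (103 higher, 106 lower), and 192 higher and 113 lower genes in DESeq2, the tool the submitters used. Groups did not overlap in 4645 genes, 26.2% of those tested, where chance gives 10%. edgeR called 92 genes (46 higher, 46 lower) among those with at least 10 CPM in 3 libraries, each at an adjusted p of 0.0495 or 0.0499, just under the threshold. Without replicate 1 labelled Selk-/- it called 59, of which 40 were lower and 35 of these were small RNA genes; without replicate 2 labelled Selk-/- it called 1, the lectin Clec10a, named after its value was seen. With the snoRNA split as a block it called 0, and 1873 genes had an unadjusted p under 0.05.

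Homeostatic microglia genes, which mark resting microglia, were lower as a list: 19 of 21 members were below WT, with a median log2 fold change of -0.19 (camera adjusted p = 2.5e-05). Adjusted over the list alone, 4 members fell, and over all genes 0 did. Those 4, named after their values were seen, were the fractalkine receptor Cx3cr1 (-0.53, 2851 ± 222 to 1977 ± 38.2 CPM, SD, n = 3 each), Sparc (-0.44), Fcrls (-0.43) and P2ry13 (-0.38). Cst3, the most abundant member, was at -0.09 and did not pass. Lysosome genes had 23 of 30 members below WT, a median of -0.11 (camera adjusted p = 0.0113) and 0 members past the threshold adjusted over the list alone; Ctsd was at -0.07. With an estimated correlation both calls were lost (adjusted p = 0.419 for each), while fry gave an adjusted p of 0.0176 for each. Blocked on the snoRNA split, the medians were -0.19 and -0.11. Without the 2 libraries titled with 2 numbers or without WT replicate 2 the lysosome call was lost (camera adjusted p = 0.06 and 0.0698), though the medians stayed at -0.11 and -0.12. Without the 2 libraries with low snoRNA counts, which leaves 1 library labelled Selk-/-, the lysosome median was -0.09.

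Antigen presentation genes were lower in 15 of 18 members, with a median of -0.36 (camera adjusted p = 4.7e-05). Adjusted over the list alone, 8 fell, among them H2-T23 and, named after their values were seen, the class II chaperone H2-DMb1 (-0.60) and H2-Ab1 (-0.83), beside H2-D1 (-0.39, 1075 ± 89.8 to 823 ± 62.2 CPM, SD, n = 3 each), and over all genes 0 did. B2m, the most abundant member, was at 0.17. With an estimated correlation the adjusted p was 0.579, and fry gave 0.0486. Blocked on the snoRNA split, the median was -0.27. Border macrophage markers (median -0.78) and summed B cell markers (232 ± 29.9 to 176 ± 16.2 CPM, SD, n = 3 each), of cells that also carry class II molecules, were lower in the same libraries. Class I and class II genes share near-identical sequence with paralogs, so single values are uncertain.

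Genes of endoplasmic reticulum stress and protein degradation, the compartment of SELENOK, were higher in 23 of 28 members, with a median of 0.18 (camera adjusted p = 5.6e-04). Adjusted over the list alone, 4 rose and over all genes 0 did: the chaperone Hspa5 (0.59, 1245 ± 151 to 1877 ± 271 CPM, SD, n = 3 each) and, named after their values were seen, Dnajb9 (0.49), Hsp90b1 (0.41) and the ubiquitin ligase Syvn1 (0.33). Atf3 was at -0.07. With an estimated correlation the adjusted p was 0.887, fry gave 0.406, and with the snoRNA split as a block the median was 0.07 and the call was lost (adjusted p = 0.370).

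Ribosomal protein genes were lower in 76 of 82 members, with a median of -0.21 (camera adjusted p = 4.2e-11); 31 fell adjusted over the list alone and 0 over all genes. Rpl13a was at -0.44 and Rps3 at -0.30, and these genes have many processed pseudogenes, so their counts are uncertain. Nuclear genes of oxidative phosphorylation were lower in 68 of 95 members, with a median of -0.07 (camera adjusted p = 0.0139); 6 fell adjusted over the list alone, with Cox4i1, named after its value was seen, at -0.62, and Atp5b (-0.07) and Atp5a1 (-0.09) did not pass. With an estimated correlation the adjusted p was 0.887 for both lists, and fry gave 0.260 and 0.542. Ribosomal and oxidative phosphorylation genes are short. Each library's log2 CPM was taken as a deviation from the gene's mean over the 6 libraries. The slope of this deviation on log2 gene length was -0.022, -0.036 and -0.013 in WT. It was -0.0075 in replicate 1 labelled Selk-/-, and 0.032 and 0.046 in replicates 2 and 3 labelled Selk-/-. Blocked on the snoRNA split, the ribosomal median was -0.13 and that of oxidative phosphorylation -0.02, which ended its call (adjusted p = 0.846). The latter call was also lost with the trend of counts with gene length removed (median -0.02, adjusted p = 0.393), without WT replicate 2 (median -0.01, adjusted p = 0.593) and without replicate 2 or 3 labelled Selk-/- (medians -0.05 and -0.03, adjusted p = 0.0970 and 0.153).

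**Figure D2:**
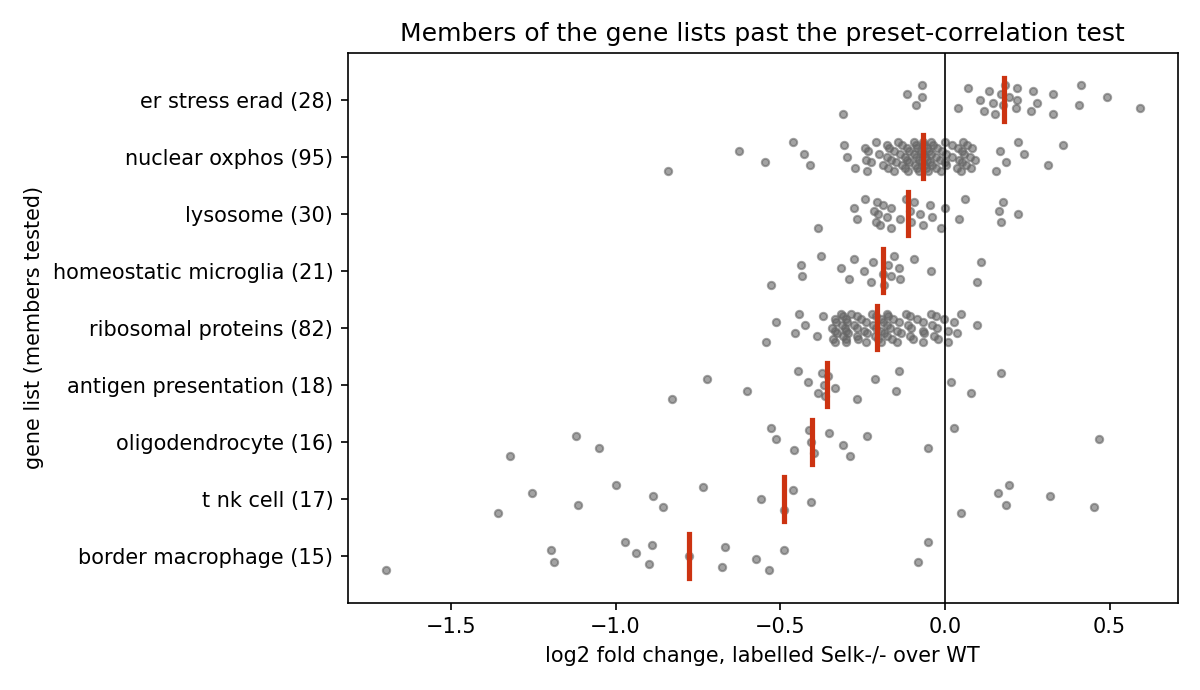
Log2 fold change of each member (points; vertical position within a list has no meaning) of the 9 lists past the preset-correlation test, with the list median as a red bar and the number of members tested in brackets. All 15 border macrophage markers lie below 0, and 23 of 28 genes of endoplasmic reticulum stress lie above 0.

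Markers of other cells differed as well. Border macrophage markers, which label the macrophages of the brain's surfaces and vessels, were lower in 15 of 15 members, with a median of -0.78 (camera adjusted p = 9.8e-06; 5 fell adjusted over the list alone). Those 5, named after their values were seen, were Cd209f (-1.70, 49.4 ± 14.99 to 15.2 ± 6.59 CPM, SD, n = 3 each), Clec10a (-1.20), Folr2 (-1.19), Siglec1 (-0.94) and Cd163 (-0.89), while the most abundant, Stab1 and Maf, which microglia also express, were at -0.05 and -0.08. T and NK cell markers had a median of -0.49 (camera adjusted p = 0.0139), with 11 of 17 lower. Cd3g, named after its value was seen, was past the threshold adjusted over the list alone. Cd4 was at -0.999 (7.59 to 3.80 CPM) and Gzma at 0.45 (2.27 to 3.11 CPM). The list's markers summed to 24.0 ± 3.80 CPM in WT and 18.3 ± 2.70 CPM in the libraries labelled Selk-/- (SD, n = 3 each). These sums overlapped between groups, and the changes rest on low counts. Oligodendrocyte markers had a median of -0.40 (camera adjusted p = 0.0311; 14 of 16 lower), with Trf at -0.24 and Mal at 0.47. With an estimated correlation the adjusted p was 0.887 for each of these 3 lists, and fry gave 0.266, 0.260 and 0.542. With the snoRNA split as a block the medians were -1.35, -0.68 and -0.18, and the oligodendrocyte call was lost (adjusted p = 0.846). Without WT replicate 2 the border macrophage median was -0.51 (adjusted p = 3.8e-04). The oligodendrocyte call was also lost without WT replicate 2 (median -0.23, adjusted p = 0.507) and without replicate 2 labelled Selk-/- (median -0.23, adjusted p = 0.0758), while the median was -0.69 without replicate 1 labelled Selk-/- (adjusted p = 0.00119). The T and NK call was lost without WT replicate 3 (median -0.38, camera adjusted p = 0.110) and without the 2 libraries titled with 2 numbers (median -0.42, camera adjusted p = 0.0551).

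Summed over each list, border macrophage markers were 2283 ± 271 CPM in WT and 1794 ± 277 CPM in the libraries labelled Selk-/-, oligodendrocyte markers 1640 ± 79.1 and 1441 ± 93.5 CPM, and B cell markers 232 ± 29.9 and 176 ± 16.2 CPM (SD, n = 3 each). These were the 3 of 13 marker sums without overlap between groups, and each had an exact permutation p of 0.1, the smallest the design allows (adjusted 0.433). Stab1 and Maf, which microglia also express, held 765 and 416 CPM of the border macrophage sum in WT. They held 738 and 393 CPM of it in the libraries labelled Selk-/-, so much of that sum is not particular to border macrophages. With DESeq2 size factors the oligodendrocyte sums overlapped. Trf alone held 1198 CPM of the mean oligodendrocyte sum in WT and 1016 CPM in the libraries labelled Selk-/-. The separation of these sums therefore rests mostly on Trf and does not speak for the other markers. Neutrophil markers were 6794 CPM in replicate 2 labelled Selk-/- and 719 to 1585 CPM in the other 5 libraries. Monocyte and dendritic markers were 830 CPM in that library and 156 to 269 CPM in the others.

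**Figure D3:**
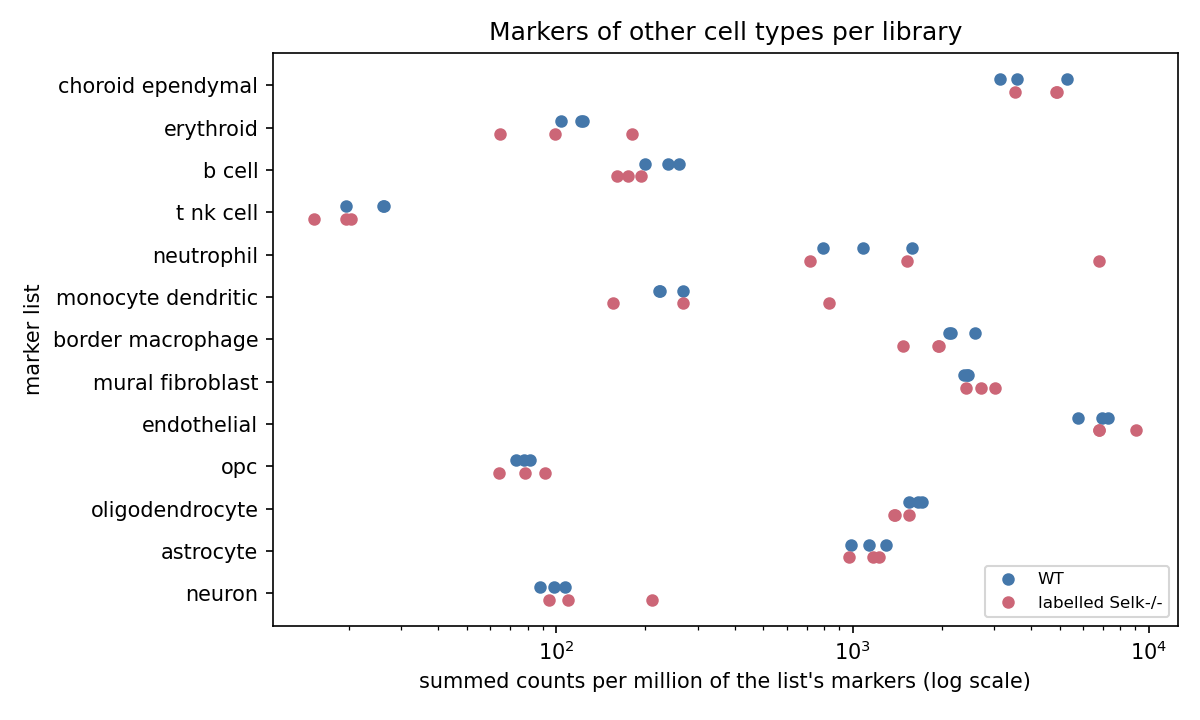
Summed CPM, on a log scale, of 13 lists of markers of other cell types in each library, WT in blue and labelled Selk-/- in red. Replicate 2 labelled Selk-/- has 6794 CPM of neutrophil markers, above the other 5 libraries.

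The remaining 25 lists did not pass. Blocked on the snoRNA split, 9 of them did, again on 1 library labelled Selk-/-. Their medians were then -0.17 for amyloid receptors (adjusted p = 0.0171), -0.20 for disease-associated microglia (adjusted p = 0.0062), -0.04 for complement, -0.47 for cell cycle, -0.55 for monocyte and dendritic, -0.68 for B cell and -0.75 for erythroid genes, and 0.45 for endothelial (adjusted p = 4.1e-06) and 0.26 for mural and fibroblast genes. Without the block, amyloid receptor genes (11 higher, 17 lower of 28; camera adjusted p = 0.622) had 3 members past the threshold adjusted over the list alone: Trem2 (-0.41), Cd36 and Itgb1 (0.34). Apart from Cd36, the members named here and for the next lists were named after their values were seen. Palmitoylation genes (9 higher, 19 lower; adjusted p = 0.778) and selenoprotein genes (7 higher, 12 lower; adjusted p = 0.347) had 0. Phagocytosis, actin and migration genes (16 higher, 17 lower; adjusted p = 0.549) had 3: Was (-0.40), Arpc4 (-0.49) and Vav1 (-0.30). Disease-associated microglia genes (6 higher, 19 lower; adjusted p = 0.0906) had 3: Trem2, Cd68 (-0.27) and Spp1 (0.41). Inflammatory cytokine genes (19 higher, 8 lower; adjusted p = 0.0906) had 1, Il6 (0.64). The median, mean and test differed in sign for 5 lists: amyloid receptors, lipid metabolism, cell cycle, dissociation and immediate early genes, and erythroid markers.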

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

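The length, GC, Xist and Ddx3y, border macrophage, snoRNA and title number alternatives were chosen after seeing the data. The number of genes past adjusted p 0.05 was 0 in edgeR, under DESeq2 size factors, library size only and no filter, in limma-voom and limma on FPKM, and in the alternatives chosen later other than the title numbers. It was 92 with at least 10 CPM in 3 libraries, where fewer genes were tested, and 972 with DESeq2. The submitters' rule, which uses an unadjusted p, took 209, and adding 2-fold to adjusted p 0.05 left 0. Leaving out each library in turn gave 0 to 59, with 59 without replicate 1 and 1 without replicate 2 labelled Selk-/-. The 92 genes were all among the 972, and 16 of the 59 were. The number of lists past the threshold was 9. It was 0 with an estimated correlation, 3 with fry and 15 with the snoRNA block, and 7 to 12 when each library was left out. The number of marker sums without overlap was 3, 2 with DESeq2 size factors, where the oligodendrocyte sums overlapped, and 3 to 5 when each library was left out, with 5 without replicate 1 labelled Selk-/-. What caused these differences between settings was not tested. The Selenok log2 fold change was -0.12 and stayed within -0.16 to -0.07 when each library was left out; no alternative called it. Among the other named genes, 4 with small changes turned sign: Atf3 (-0.143 to 0.0451 when each library was left out, the highest without replicate 1 labelled Selk-/-, 0.0038 with the GC trend removed, and 0.00346 with and 0.00429 without the replicate block), Maf (0.0171 and 0.0156 likewise), Ctsd (0.0137 with the GC trend removed) and Stab1 (-0.156 to 0.0232 when each library was left out, above 0 without WT replicate 2, 0.0232, and without replicate 1 or 2 labelled Selk-/-, 0.015 and 0.0224, and 0.0306 with the GC trend removed). The titles share the numbers 3 (WT replicate 1, replicate 3 labelled Selk-/-) and 6 (replicate 2 of each group). Deviations from the group means correlated at 0.141 and -0.128 in these pairs, and at -0.155 to 0.224 in the other pairs across groups. So few correlations cannot decide whether the numbers pair the libraries. A replicate block on these 4 libraries called 19 genes and 10 lists, and the same 4 without it 29 and 9. In these 4 the snoRNA split and the label coincide, and 12 of 13 lower calls with the block and 24 of 25 without it were small RNA genes. Depth limits genes near 0.142 CPM or less, the level of 3 counts in the smallest library.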

Other observations

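The genes, gene groups and tests in this part were chosen after the data were seen, except the counts of splits; the bounds of the length and GC tests and of the test of Cd36 with a border macrophage covariate were set before those tests were run. Heat shock genes were higher in 20 of 20 members in the libraries labelled Selk-/-, with a median log2 fold change of 0.62. Examples are Hsph1 (73.6 to 184 CPM), Dnaja1 (273 to 595 CPM) and Chordc1 (72.7 to 146 CPM). Relative to the WT mean, the list's mean log2 CPM was 0.28, 0.86 and 0.75 in replicates 1 to 3 labelled Selk-/-, and -0.23 to 0.14 in WT. Replicates 2 and 3 labelled Selk-/- are the libraries with low snoRNA counts. Genes that respond to glucocorticoids were higher in 18 of 20 members, with a median of 0.36. Zbtb16 went from 8.32 to 39.7 CPM and Fkbp5 from 118 to 311 CPM. Camera gave an unadjusted p of 7.3e-10 and 1.3e-06 for these 2 lists, and 0.14 for each with an estimated correlation. As both lists were written after the data were seen, these p-values are not valid tests of them. Blocked on the snoRNA split, on 1 library labelled Selk-/-, the medians were 0.22 and 0.64.

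The acute-phase gene Serpina3f was at 3.59, 27.7 and 11.9 CPM in replicates 1 to 3 labelled Selk-/- and at 0.781 to 0.892 CPM in WT. The vascular adhesion gene Sele was at 49.2 CPM in replicate 2 and 14.9 CPM in replicate 3 labelled Selk-/-, and at 1.36 to 2.14 CPM in the other 4 libraries. Xist was at 0.213 CPM in WT replicate 1 and 0.155 CPM in replicate 2 labelled Selk-/-, and Ddx3y at 0.113 CPM in WT replicate 2 and 0.953 CPM in replicate 1 labelled Selk-/-. Both genes were present in replicate 3 of each group, the libraries titled with 2 numbers (Xist 281 and 260 CPM, Ddx3y 53.1 and 75.3 CPM). Xist, a mark of females, was at 345 CPM in WT replicate 2 and 419 CPM in replicate 1 labelled Selk-/-. Ddx3y, on the Y chromosome, was at 118 CPM in WT replicate 1 and 165 CPM in replicate 2 labelled Selk-/-. Each group thus mixed libraries with male and female marks, which argues against repeats of the same animal.

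Selenok kept nearly its WT count in the libraries labelled Selk-/-. An exchange of labels between groups, with a knockout that removes the transcript, is argued against by the lowest library holding 86.6% of the highest. Reads from pseudogenes are argued against by their rows holding at most 0.0979% of the Selenok count. An allele that leaves a transcript, and wrong labels that involve samples outside the 6, stay open as untested explanations.

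Border macrophage markers and Cd36 were lower together; that 100% of the 15 markers were lower restates the pattern, so a lower share of these cells and lower expression per cell cannot be told apart. A trend with gene length is argued against, as the list's median stayed at -0.71 with it removed. For Cd36, a lower endothelial share is argued against by an endothelial median of 0.19, which ran from 0.0683 to 0.344 when each library was left out. With the border macrophage score as a covariate, the Cd36 log2 fold change was -0.26 (95% interval -0.78 to 0.27). The score itself separated the groups, so adjusting for it also removes part of the label difference and cannot decide the question. A lower share of border macrophages stays open. With the snoRNA split as a block the values were -1.35 for the list and -1.24 for Cd36, but 1 library labelled Selk-/- carries both, so the split and the label cannot be told apart. Regulation by genotype in these cells stays open and was not tested.

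Ribosomal and homeostatic microglia genes were lower as lists at the preset correlation, but not with an estimated one (camera adjusted p = 0.887 and 0.419). With the length trend removed the medians went from -0.21 to -0.15 and from -0.19 to -0.16. Both calls at the preset correlation stayed, which argues against length as the whole cause. That reading was chosen after the values were seen, as the bound of -0.15 set beforehand was passed by less than the standard error of the median over members (0.019 and 0.0436), and part of the ribosomal shift moved with length. With the snoRNA split as a block they were -0.13 and -0.19, again resting on 1 library labelled Selk-/-, which leaves a library preparation difference open. A GC trend as the whole cause of the ribosomal shift is argued against by a median of -0.18 with it removed. A difference by genotype stays open and was not tested.

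A segment of another strain around the edited gene was tested as a hypothesis. Of 93 genes tested within 5 Mb of Selenok, 8.60% had an unadjusted p under 0.01, below the 95th percentile of such windows (12.4%), which argues against a dense cluster of differences there. Syt15 lies in that window.

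The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. For genes past adjusted p 0.05 in edgeR the real value was 0, the highest other 1, and 10 of the 10 splits gave as many. For genes at unadjusted p under 0.05 the real value was 3383 and the highest other 1202, and 1 split, the real one, gave as many. For DESeq2 the real value was 972 and the highest other 34, and 1 split gave as many. For lists the real value was 9 and the highest other 13, and 8 of the 10 splits gave as many. The number of lists past the preset-correlation test therefore did not set the labelled groups apart from other splits.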
